A study of Mus musculus with 18 samples.

How the data were processed

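RNA and accessible chromatin (ATAC) were measured in pro-B cells from mouse fetal liver of 3 genotypes (WT, Ebf1-KO and Pax5-KO), with 3 libraries per genotype and assay and 18 in all. Per the labels, RNA libraries were made with the NuGEN Ovation Ultralow kit and read for 76 cycles, and ATAC libraries were made from 80 k cells with Nextera transposase. The submitters name Bowtie2 and HOMER for ATAC, and TopHat, HOMER, edgeR and DESeq2 for RNA, on build mm10 (GRCm38). Versions of these tools are not given in the sources used here. Samples were grouped by the genotype and replicate number in their titles and by the sample names in the file headers.

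Per the file headers, the authors' gene table holds reads over exons, condensed to 1 transcript per gene and normalized to 10 M mapped reads in each library (M, 1e6). The value of 1 read was estimated in each library from its low values, since the headers give it only rounded. Divided by this estimate, 99.6 to 100% of the values were whole to within 0.1 reads, so reads could be recovered. The mapped reads given below follow from the same estimate. The ATAC tables hold, per the file headers, the signal per peak from the authors, tags scaled to 10 M per library, for EBF1-only, PAX5-only and shared ChIP peaks. Mitochondrial reads had been left out, per the directory names in the headers. The peak score in the deposited peak lists is the authors' own, from re-analysed published ChIP data (1 EBF1 data set and 3 combined PAX5 data sets). The other distance values, in bp to the nearest start site, were deposited by the authors from HOMER's annotation. The pooled profiles hold coverage per bp per peak in bins of 25 bp, as deposited. The profile at sites near progenitor genes came from combined tag directories, per the file headers, and for the other profiles it is not given in the sources used here whether libraries were pooled or averaged. The log2 fold changes and the adjusted p-values (FDR) of the gene tables were deposited by the authors, made by HOMER with 1 entry per transcript, and give the knockout over WT.

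The plan fixed before the data were examined named the comparisons, tests, gene lists, key genes and most alternatives. It named edgeR for read counts and limma where a table held normalized values. Since the tables were normalized, RNA and ATAC were tested with limma (trend) on log2(value + 1) with the authors' scaling kept. One model over 9 libraries had a mean per genotype. Genes passed edgeR's filterByExpr on the recovered reads, and peaks with under 10 reads in all were left out. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Of 14377 peaks 14365 were tested. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

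The 19 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons. Class medians of ATAC signal are medians over peaks of the log2 ratio of group means with 0.5 added. Class means per library were compared by exact two-sided permutation, which with 3 against 3 libraries cannot give a p below 0.1. Bound genes were tested by two-sided Fisher's exact test over 8 adjusted tests. The overlap of both knockouts was set against 100 simulations of unchanged groups and 100 regroupings of the libraries, and another 100 that kept 1 library of each number per group. Named genes were the 22 key genes, the 6 largest rises and falls per comparison among called genes with a mean of at least 5 CPM and groups that did not overlap, and up to 4 called members per list. Named peaks were the peak of highest WT signal per key gene and the 3 largest rises and falls. A group at 0 was given a floor of 3 reads over the group (0.236 in WT, 0.247 in Ebf1-KO and 0.193 in Pax5-KO), and a list's median was repeated with such genes at that bound. The EBF1 palindrome TCCCNNGGGA was sought on both strands in 14372 peaks of the mm10 sequence, with 5 not scanned.

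Reads in exons ranged from 15.6 to 63.6 M per RNA library. They were 47.0, 55.1 and 59.3% of mapped reads in WT 1, 2 and 3, 62.3, 60.5 and 69.8% in Ebf1-KO, and 55.5, 61.2 and 71.4% in Pax5-KO. Within groups the log2 values correlated with r from 0.990 to 0.996, and the spread between libraries was 4.57 to 49.3 times that of counting alone. ATAC libraries correlated with r from 0.869 to 0.932 within groups and from 0.562 to 0.789 between them.

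The method was tested on simulated data of the same size with known changes. Few features were changed, as many up as down, with no shift in scaling and no pairing. The shares below therefore need not hold for the real data. For RNA, changes of 1.5, 2 and 4 times were called in 28.4, 83.6 and 100% of changed genes for Ebf1-KO against WT, and in 13.4, 77.6 and 98.5% for Pax5-KO against WT. For the direct contrast the shares were 26.9, 80.6 and 100%. Of the calls 4.73, 3.82 and 8% were false. For ATAC the shares were 1.49, 34.3 and 97.0% in Ebf1-KO and 2.99, 32.8 and 98.5% in Pax5-KO, with 3.30 and 6.32% false. No call had the wrong sign. A changed set of 20 genes was called by camera in each comparison, and of 50 unchanged sets 0, 0 and 1 had camera p under 0.05. The simulated genes were drawn independently, so these sets cannot show how the preset correlation serves lists with correlated members. In the real lists the estimated correlation ranged from 0.0043 to 0.87.

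The replicate numbers were checked for pairing across genotypes. In RNA all 9 pairs of the same number had residual correlations over 0.1 (0.116 to 0.439, others -0.366 to 0.0300). In ATAC 1 of 9 did (-0.0523 to 0.110). The number was used as a block in an alternative and not in the test reported. This was because no label says that it stands for a shared culture or day. In RNA the test reported therefore leaves the spread shared by a number in its error, as do the fits without 1 library. With the block all 7095, 5976 and 3962 genes called in Ebf1-KO, Pax5-KO and the direct contrast kept their calls. Of the results of named genes 267 stayed the same and 1 gained a call.

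Alternatives were edgeR, DESeq2, TMM scaling, quantile normalization, other filters, pseudocounts of 0.1 and 5, a test against a fold change of 1.5, the replicate block, only the 2 groups compared, genes on X and Y left out, and each library left out. For lists, an estimated correlation and fry were added. For ATAC classes, pseudocounts of 1 and 5, peaks above the median WT signal and peaks beyond 1 kb of a start site were used. For bound genes, they were a distance of 20 kb, expression strata, a score above the median and TMM calls. Profiles were also averaged over 100 and 500 bp. The edgeR and TMM fits of RNA, the fit without X and Y, the scalings and left-out libraries of the list tests, TMM calls for bound genes, the edgeR fit of ATAC and the direct ATAC contrast were chosen after seeing the data.

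Not used here were 36 per-sample columns of the authors' gene tables, 402 bin columns whose headers carry no sample name and 4 strand columns of a profile, 442 in all. The table of progenitor sub-fractions was not analysed here. Some of the genes and sites that these rules name are not reported here, while they stay in the counts and list tests.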

Results

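Pro-B cells grown from C57BL6/J mouse fetal liver on OP9 stroma, with KIT ligand, FLT3 ligand and interleukin-7, were compared in 3 genotypes: wild type (WT), Ebf1-deficient (Ebf1-KO) and Pax5-deficient (Pax5-KO). Both genes encode transcription factors of the B lineage. The question was how loss of either factor alters gene expression and chromatin accessibility at the sites that EBF1 and PAX5 bind. RNA and accessible chromatin (ATAC) were each sequenced in 9 libraries, 3 per genotype. RNA libraries held an estimated 27.3 to 89.1 M mapped reads (M, 1e6), and ATAC libraries 15.3 to 38.6 M tags. RNA values below are reads per 10 M mapped reads, as mean ± SD of 3 libraries. Log2 fold changes were computed on value + 1, which understates the change of low genes. Over the 12839 genes tested, the median log2 fold change over WT was 0.31 in Ebf1-KO and 0.28 in Pax5-KO, and that of Ebf1-KO over Pax5-KO was 0.05. Each log2 fold change of RNA below is given less this median. Calls, directions and p-values of single genes test the change before that subtraction, so a small printed change need not match its p. Nothing in the labels says whether the libraries came from separate cultures or animals, so the p-values measure the spread between these samples.

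The targeted genes were examined first in every library. Pax5 was at 1521 ± 179 in WT, 109 ± 17.5 in Pax5-KO (log2 fold change -4.07, SE 0.21, limma adjusted p = 8.98e-10) and 13.1 ± 3.96 in Ebf1-KO (-7.10, SE 0.21, adjusted p = 6.64e-13). Ebf1 was at 3969 ± 634 in WT, 1465 ± 131 in Ebf1-KO (-1.73, SE 0.15, adjusted p = 9.05e-07) and 1515 ± 170 in Pax5-KO (-1.66, SE 0.15, adjusted p = 1.97e-06). Ebf1 transcripts thus fell in both knockouts, and the direct contrast between them did not pass (-0.09, adjusted p = 0.87). The table counts reads over all exons of a gene, so it cannot show whether the deleted part of Ebf1 or Pax5 was missing. For Ebf1 the level alone therefore does not separate the genotypes, while Pax5 does.

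**Figure D1:**
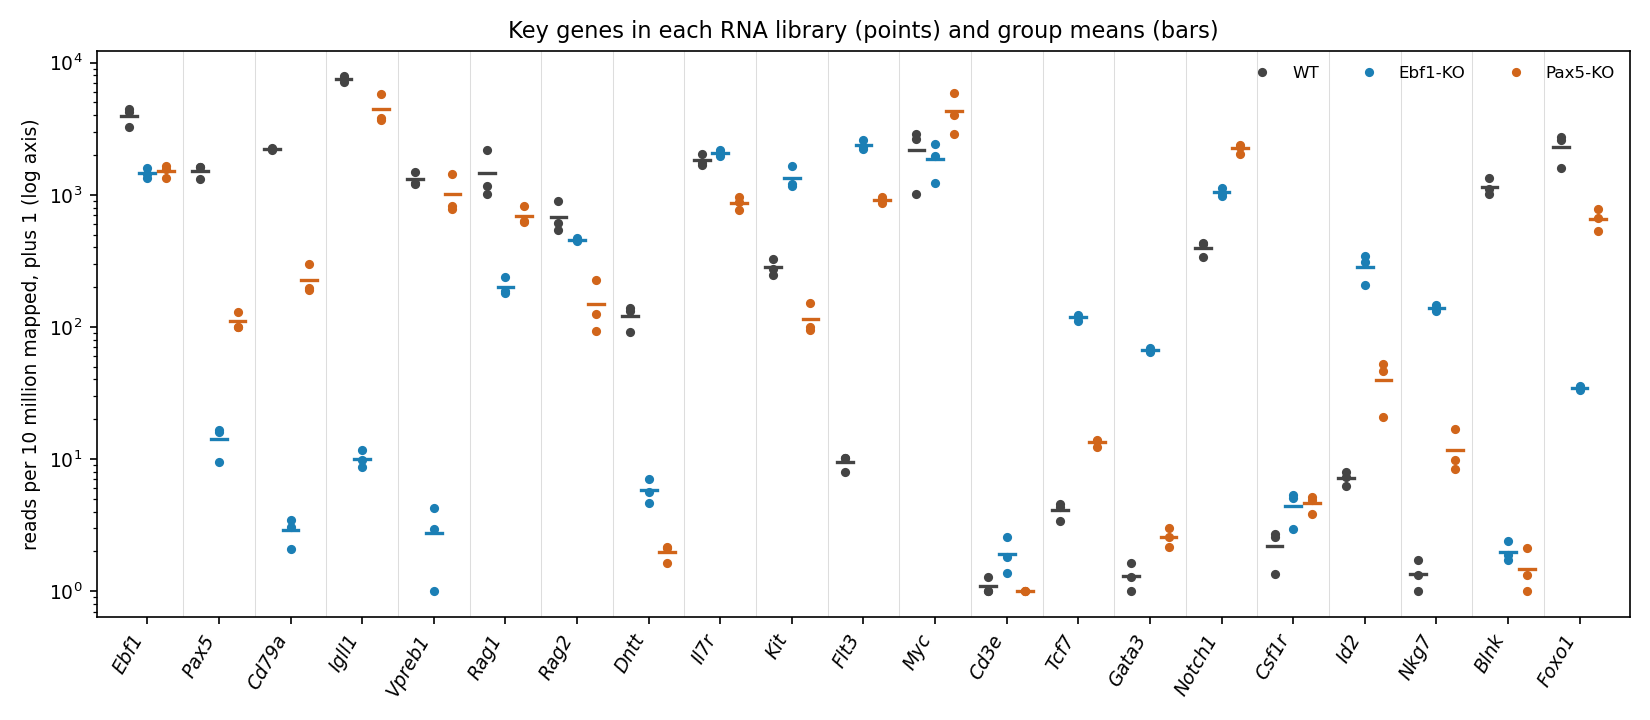
Reads per 10 M mapped reads plus 1, on a log axis, of the key genes shown in each library (points) with group means (bars) for WT, Ebf1-KO and Pax5-KO. Blnk is near the floor in both knockouts, while Igll1 is at 9.06 in Ebf1-KO and 4428 in Pax5-KO.

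The comparison of Ebf1-KO with WT asked which genes depend on EBF1 in these cells. Most components of the pre-B cell receptor fell in Ebf1-KO, several of them to near 0. Igll1, which encodes the surrogate light chain lambda5, fell from 7560 ± 375 to 9.06 ± 1.51 (log2 fold change -9.87, SE 0.17), and Cd79a, a signalling chain of the receptor, from 2226 ± 45.2 to 1.88 ± 0.707 (-9.93, SE 0.21). Vpreb3 was at 852 ± 118 in WT and at 0 in all Ebf1-KO libraries, at least 3455-fold lower (floor of 3 reads over the group). Of the 20 tested members of the pre-B and B cell receptor list, 15 fell, 1 rose and 4 did not pass (15 and 1 adjusted over the list alone). The list median was -6.17 (-6.28 with 2 genes at 0 in a group set to their bound), with camera adjusted p = 2.56e-13, and adjusted p = 0.162 with an estimated correlation.

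Transcription factors of the B lineage followed. Of 17 tested members, 13 fell and 2 rose (13 and 2 adjusted over the list alone; list median -2.92, camera adjusted p = 1.87e-10, and adjusted p = 0.162 with an estimated correlation). Pou2af1, a B cell co-activator of octamer-binding factors, fell from 20457 to 9.84 (-11.18). Erg, an ETS factor, fell from 2155 to 4.34, and Foxo1, which acts upstream of Rag gene transcription, from 2298 ± 625 to 33.5 ± 1.28 (-6.32). In the V(D)J recombination list 7 of 14 members fell and 2 rose (7 and 2 adjusted over the list alone; median -0.82, camera adjusted p = 0.00164, and adjusted p = 0.321 with an estimated correlation). With TMM scaling 11 members fell and 1 rose. Rag1, which encodes a subunit of the recombinase, fell from 1459 ± 643 to 201 ± 32.9 (-3.09), and Dntt, the terminal transferase, from 119.5 to 4.79 (-4.68). Rag2 was at 682 ± 184 in WT and 456 ± 14.6 in Ebf1-KO and did not pass (-0.85, adjusted p = 0.0854). It passed with TMM scaling, quantile normalization, DESeq2, edgeR, the replicate number as a block or only the 2 groups compared, and without Pax5-KO 1 (adjusted p = 0.0344) or Pax5-KO 3 (0.0133).

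Genes of other lymphoid lineages were higher in Ebf1-KO. All 17 tested members of the NK and innate lymphoid list rose (17 adjusted over the list alone; median 5.56, camera adjusted p = 2.2e-10, and adjusted p = 0.162 with an estimated correlation). Id2, an inhibitor of E proteins, rose from 6.21 ± 0.871 to 284 ± 70.8 (4.97), Il2rb, a chain of the IL-2 and IL-15 receptors, from 0.381 to 577 (8.41), and Nkg7, a cytotoxic granule gene, from 0.340 to 137.5 (6.42). Of 15 tested T lineage genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; median 3.55, or 3.67 with 1 gene at its bound; camera adjusted p = 4.43e-05, and adjusted p = 0.162 with an estimated correlation). Tcf7 rose from 3.09 to 116.8 ± 6.23 (4.55) and Gata3 from 0.305 ± 0.318 to 65.6 ± 2.79 (5.39), both regulators of early T cell development. Bcl11b rose from 0.106 to 173, and Notch1 from 395 to 1045 (1.10). Hes1 was the member that fell, from 37.4 to 1.19 (-4.66). Cd3e was not tested, with a mean of 0.914 in Ebf1-KO and 0.0933 in WT.

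Progenitor genes rose as well, 11 of 14 in the stem and multipotent progenitor list with none lower (11 adjusted over the list alone; median 2.44, camera adjusted p = 5.51e-05, and adjusted p = 0.162 with an estimated correlation). Flt3, the receptor of one of the added cytokines, rose from 8.46 ± 1.29 to 2361 ± 189 (7.66, SE 0.14), Cd34 from 0.779 to 2156 (9.94), Hoxa9 from 0.439 to 566 (8.35) and Kit from 282 ± 41.4 to 1342 ± 268 (1.93). Of 14 myeloid genes 9 rose and 3 fell (9 and 3 adjusted over the list alone). The myeloid list did not pass (median 2.42, camera adjusted p = 0.0562, range 0.0158 to 0.529 over the camera alternatives). It passed with TMM scaling, with quantile normalization and without WT 1, WT 2, Ebf1-KO 1 or Ebf1-KO 3 (0.0245 without WT 1). Mpo, the neutrophil granule peroxidase, rose from 0.0933 to 174 and Tyrobp from 0.633 to 835 (8.69). Of 8 dendritic cell genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 4.57, camera adjusted p = 0.0691, range 0.0147 to 0.289). This list passed with TMM scaling, with quantile normalization and without WT 1 or Ebf1-KO 3 (0.0363 without Ebf1-KO 3). Ccr9, a chemokine receptor of thymus-seeding cells, rose from 17.4 to 10593 (8.87), and Itgax was at 62.1 ± 8.67 against 0 in all WT libraries, at least 263-fold higher. In the erythroid and megakaryocyte list 6 of 7 rose, from low levels, and 1 fell (6 and 1 adjusted over the list alone; median 2.31, or 2.37 with 1 gene at its bound; adjusted p = 0.109, range 0.0385 to 0.286, the lowest with TMM scaling). Hbb-bt rose from 2.98 to 24.8 and Gp9 from 0.0530 to 6.83. The member Hbb-b2 had nearly the same values as Hbb-bt in every library (mean 25.0 in Ebf1-KO), so these members may not be separate evidence in any comparison.

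Survival and adhesion genes moved in both directions. In the interleukin-7, KIT and FLT3 signalling list 8 rose, 3 fell and 6 did not pass (8 and 3 adjusted over the list alone; median -0.07, mean 0.28, test upward, camera adjusted p = 0.601). Bcl2, an inhibitor of apoptosis, rose from 350 ± 68.1 to 6758 ± 1493 (3.96) and Pim2 from 85.1 to 913 (3.07), while Ccnd3, a D-type cyclin, fell from 1657 to 488 (-2.05). Il7r was at 1821 ± 175 in WT and 2079 ± 115 in Ebf1-KO and did not pass (adjusted p = 0.232). Of 17 adhesion and homing receptors 12 rose and 3 fell (12 and 4 adjusted over the list alone; median 1.19, adjusted p = 0.26). Ccr2 rose to 640 (6.85) and Cd55 fell from 211 to 0.214 (-7.77). Of 20 cell cycle genes 4 fell, 2 rose and 14 did not pass (4 and 2 adjusted over the list alone, and 14 and 2 with TMM scaling; median -0.37, adjusted p = 0.0929, range 0.00321 to 0.899). This list passed with the replicate number as a block (0.0467), with TMM scaling, with quantile normalization, and without Ebf1-KO 3 (0.0336). Mki67, a proliferation marker, fell from 24644 to 14315 (-1.10).

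The remaining lists did not pass in Ebf1-KO. Interferon response genes rose in 7 of 9 cases and fell in 1 (7 and 1 adjusted over the list alone; median 1.00, adjusted p = 0.237): Irf7 rose from 6.96 to 20.9 (1.17), and Ifit2 fell from 128 to 4.55 (-4.85). In the glycolysis and glucose uptake list 6 of 18 rose and 3 fell (6 and 2 adjusted over the list alone, and 4 and 6 with TMM scaling; median -0.17, adjusted p = 0.569), among them Pfkm, which rose (1.18), and Aldoc, which fell (-1.29). Immediate early and stress genes rose in 4 of 11 cases and fell in 2 (4 and 2 adjusted over the list alone; median 0.06, mean -0.18, test downward, adjusted p = 0.569). In the Myc and ribosome biogenesis list 1 of 16 passed, Odc1 (0.16, adjusted p = 0.0427), and none adjusted over the list alone (median -0.21, adjusted p = 0.535). With TMM scaling none was higher and 6 were lower. The Odc1 call was lost with TMM scaling, quantile normalization, edgeR or DESeq2, and without WT 1, WT 2, Ebf1-KO 1, Ebf1-KO 2, Ebf1-KO 3 or Pax5-KO 2 (adjusted p = 0.182, 0.0622, 0.0647, 0.0568, 0.161 and 0.0615). Myc itself was at 2172 ± 1013 in WT and 1875 ± 607 in Ebf1-KO (adjusted p = 0.778). Of 11 stroma and fibroblast genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median -0.51, mean 0.12, test downward, adjusted p = 0.569). The risen members included Pdgfrb, from 0.523 to 373 (7.73). Stroma transcripts varied between libraries, Col1a2 from 0.550 to 12.7, Cxcl12 from 0 to 28.2 and Fn1 from 3.42 to 144, each highest in replicate 2 of every group. Acta2 was at 93.7 to 135 in WT. None of the 11 hepatocyte genes was high enough to be tested.

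All 3 Ebf1-KO libraries also differed from the other 6 in sex-linked transcripts. Xist, transcribed from the inactive X chromosome, was between 41026 and 47861 in Ebf1-KO and between 1.59 and 42.8 elsewhere. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at most 2.75 in Ebf1-KO and between 389 and 1081 elsewhere. All 5 members passed (1 rose, 4 fell; the same counts adjusted over the list alone; median -8.32, camera adjusted p = 7.64e-05, and adjusted p = 0.162 with an estimated correlation). Other large changes were rises of Igf2, a fetal growth factor (from 13.6 to 21227, 10.22), and Cd163l1 (from 0.901 to 2074, 9.84), and falls of Enpep (from 5409 to 2.06, -11.10), Cd36 (from 2262 to 0.428, -10.96) and Tead1 (from 2017 to 0.359, -10.88).

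In all, 7095 of 12839 genes were called in Ebf1-KO (limma, adjusted p under 0.05), 5240 higher and 1855 lower. With TMM scaling 7460 were called, 3851 higher and 3609 lower, so the balance of directions rested on the scaling. DESeq2 gave 4113 higher and 3597 lower, edgeR 3809 and 3570, and quantile normalization 3665 and 3910. Under both the authors' and TMM scaling 3851 genes were higher and 1853 lower. Relative to the median, 1948 called genes were over 2-fold higher and 1490 over 2-fold lower. All 3 libraries of a group lay beyond the other 3 for 8265 genes (64.4%), against 10% by chance. None of the 26 list calls of the 3 RNA comparisons held with an estimated correlation (camera; 14 of 54 tests at an unadjusted p under 0.05). With fry, which tests a list against no change and not against other genes, 33 were called, among them 24 of the 26. The 2 lost were cell cycle in Pax5-KO (fry adjusted p 0.63) and Myc and ribosome biogenesis in the direct contrast (0.289). The 9 others called by fry were myeloid, dendritic, erythroid, cytokine signalling, adhesion and interferon genes in Ebf1-KO, adhesion in Pax5-KO, and myeloid and dendritic in the direct contrast. As the median gene was up by 0.31 in Ebf1-KO, fry may favour upward calls there. Cytokine signalling was called upward (fry adjusted p = 0.00559) with a list median of -0.07 and mean of 0.28 relative to all genes. Adhesion in Pax5-KO was called downward, against such a shift. The estimated correlation gave the highest p of all alternatives for each of the 26.

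**Figure D2:**
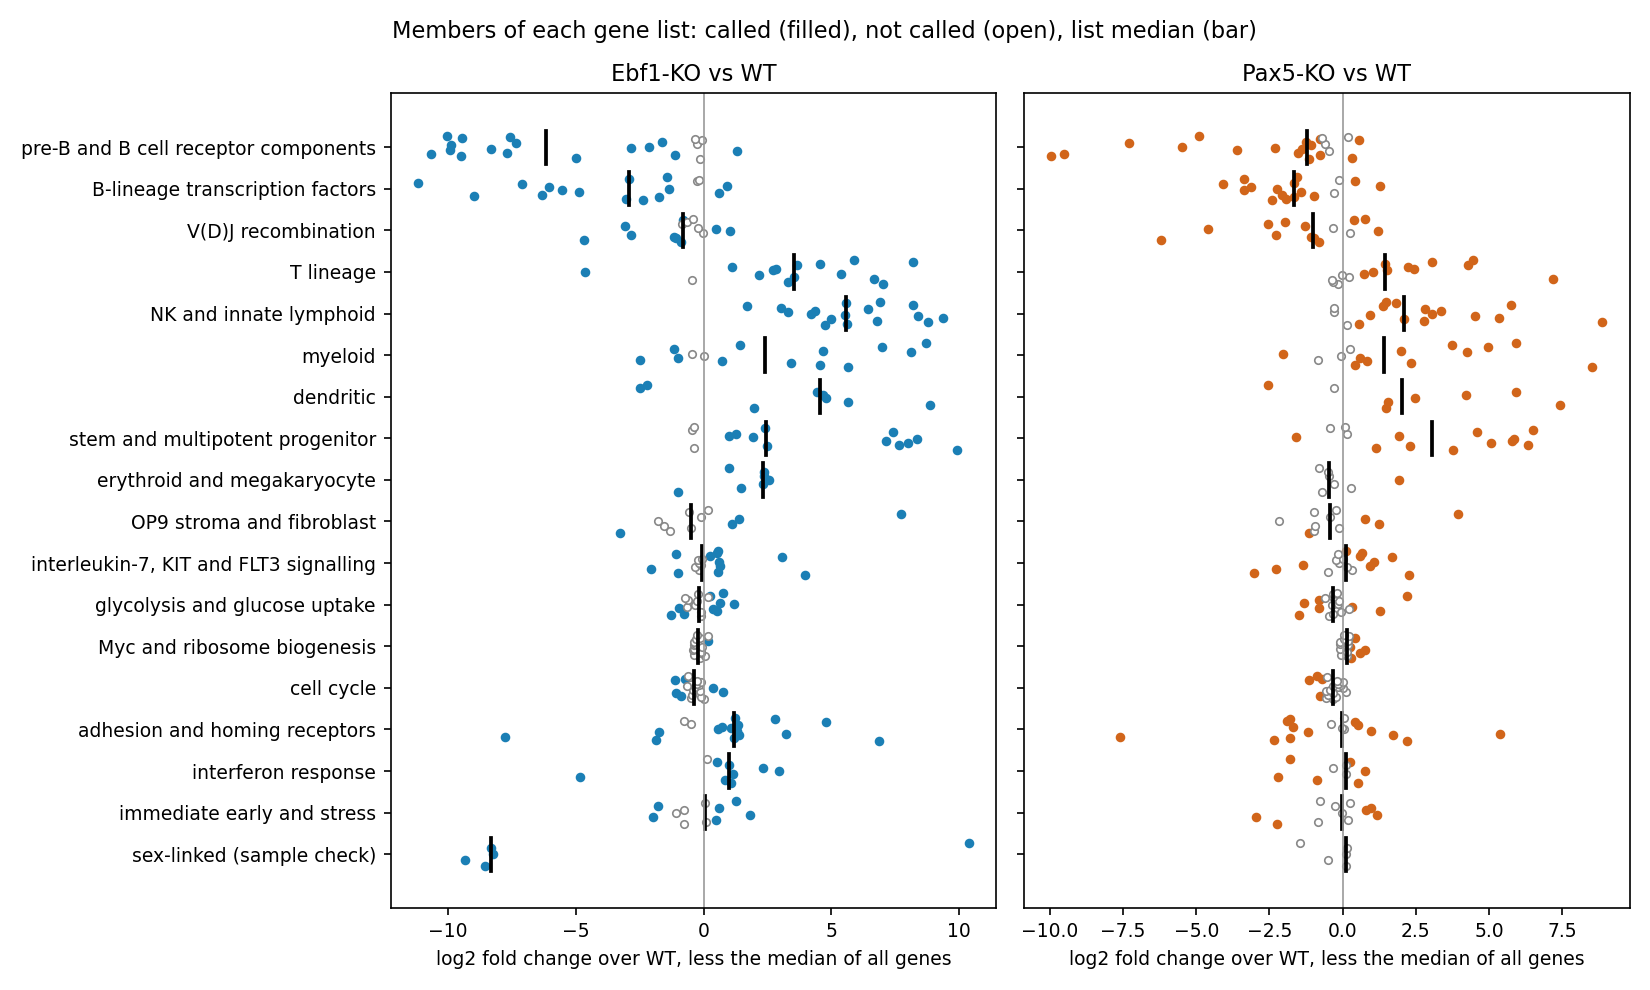
Log2 fold change over WT less the median of all genes (x axis) of each tested member of the 18 gene lists with tested members, in Ebf1-KO (left) and Pax5-KO (right); filled points passed the test, open points did not, and bars are list medians. The NK and innate lymphoid list has medians of 5.56 and 2.09, and the pre-B and B cell receptor list -6.17 and -1.20.

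The comparison of Pax5-KO with WT asked the same for PAX5. Pre-B receptor genes fell unevenly. Blnk, an adaptor of the receptor, fell from 1151 ± 167 to 0.480 ± 0.578 (-9.95, SE 0.27). Cd79a fell to 227 ± 59.7 (-3.60) and Igll1 only to 4428 ± 1175 (-1.08, adjusted p = 0.00147). Vpreb1 was at 1007 ± 361 against 1306 ± 152 in WT and did not pass (-0.70, adjusted p = 0.383). It passed with edgeR and DESeq2. Of 20 members of the list 14 fell and 2 rose (15 and 3 adjusted over the list alone; median -1.20, camera adjusted p = 2.2e-10, and adjusted p = 0.162 with an estimated correlation). Among 17 B-lineage transcription factors 13 fell and 2 rose (13 and 2 adjusted over the list alone; median -1.66, camera adjusted p = 3.35e-09, and adjusted p = 0.162 with an estimated correlation). Irf4 fell from 3177 to 373 (-3.35), Lef1 from 1556 to 214 (-3.14) and Foxo1 to 659 ± 124 (-2.06). In the V(D)J recombination list 9 of 14 fell and 3 rose (9 and 4 adjusted over the list alone; median -1.02, camera adjusted p = 3.1e-04, and adjusted p = 0.289 with an estimated correlation). Dntt fell to 0.965 ± 0.287 (-6.20), Polm, another polymerase of end joining, from 26.4 to 0.340 (-4.59), and Rag2 to 148 ± 69.7 (-2.54). Il7r fell to 869 ± 96.7 (-1.35) and Kit to 114 ± 31.6 (-1.60).

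Genes of other lineages also rose in Pax5-KO. Of 17 NK and innate lymphoid genes 14 rose and none fell (14 adjusted over the list alone; median 2.09, or 2.77 with 1 gene at its bound; camera adjusted p = 2.82e-05, and adjusted p = 0.162 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, rose from 1.95 ± 1.74 to 1566 ± 530 (8.87) and Tox from 2.96 to 253 (5.75). Of 15 T lineage genes 10 rose and none fell (10 adjusted over the list alone; median 1.44, camera adjusted p = 0.00206, and adjusted p = 0.281 with an estimated correlation). Cd28, a co-stimulatory receptor, rose to 1546 ± 252 (7.20) and Notch1 from 395 ± 51.9 to 2244 ± 177 (2.23). Tcf7 rose to 12.4 ± 0.872 (1.44). Of 14 stem and progenitor genes 10 rose and 1, Kit, fell (10 and 1 adjusted over the list alone; median 3.04, camera adjusted p = 5.48e-05, and adjusted p = 0.162 with an estimated correlation). Flt3 rose to 917 ± 46.3 (6.33), Hoxa9 to 97.5 ± 11.1 (5.86), and Hoxa7 was at 67.3 against 0 in all WT libraries, at least 285-fold higher. Of 14 myeloid genes 10 rose and 1 fell (10 and 2 adjusted over the list alone; median 1.41, camera adjusted p = 0.0056, and adjusted p = 0.317 with an estimated correlation), among them Cd33 (from 0.422 to 637, 8.53) and Mpo (to 40.8, 4.97). Of 8 dendritic cell genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 2.02, or 2.84 with 1 gene at its bound; camera adjusted p = 0.0173, and adjusted p = 0.235 with an estimated correlation). Siglech, a receptor of plasmacytoid dendritic cells, rose from 0.146 to 83.1 (5.92).

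The cell cycle list was lower in Pax5-KO, with 4 of 20 members falling and none rising (2 adjusted over the list alone, and 12 with TMM scaling; median -0.34, camera adjusted p = 0.0324, and adjusted p = 0.823 with an estimated correlation). The list call was lost without WT 3 (0.0581), Pax5-KO 1 (0.0719) or Pax5-KO 2 (0.0588). Mki67 fell to 13552 (-1.15) and Top2a from 14395 to 9489 (-0.88). The calls of the other members were lost without 1 library: Ccna2 without WT 2, WT 3, Pax5-KO 1 or Pax5-KO 2 (adjusted p = 0.0789, 0.101, 0.11 and 0.0782), and Pcna without these or Ebf1-KO 1 or 2 (0.104, 0.121, 0.157, 0.0719, 0.0574 and 0.0575). In the Myc and ribosome biogenesis list 5 of 16 rose (4 adjusted over the list alone; median 0.17, adjusted p = 0.402). Gnl3 rose from 1254 to 2238 (0.58). The other calls were lost without WT 1 or Pax5-KO 3: Myc (4288 ± 1531, 0.78; adjusted p = 0.141 and 0.0978), Polr1b (0.093 and 0.0593), Nolc1 (0.122 and 0.0888) and Bop1 (0.174 and 0.222). Myc also lost its call without Pax5-KO 2 (0.0566), and Bop1 without WT 2, Ebf1-KO 1, Ebf1-KO 2 or Pax5-KO 2 (0.0948, 0.0548, 0.0626 and 0.0532). With edgeR or DESeq2 the calls of Myc, Nolc1 and Bop1 were lost too.

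The other lists did not pass in Pax5-KO. Adhesion and homing receptors split, 6 higher and 7 lower of 17 (6 and 7 adjusted over the list alone; median -0.01, adjusted p = 0.0766, range 0.0317 to 0.334, the lowest without Pax5-KO 1). Cxcr3 was at 50.1 against 0 in all WT libraries, at least 212-fold higher, and Ccr7 fell from 219.8 to 51.5 (-2.34). In the interleukin-7, KIT and FLT3 signalling list 7 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.12, adjusted p = 0.865). Bcl2 rose to 2024 ± 284 (2.26) and Bcl2l1, its relative, fell from 129 to 19.0 (-3.03). In the glycolysis list 3 rose and 4 fell of 18 (3 and 4 adjusted over the list alone, and 3 and 9 with TMM scaling; median -0.32, adjusted p = 0.239). Slc2a3, a glucose transporter, rose from 54.3 to 304 (2.21), and Pfkp, a phosphofructokinase, fell from 160.1 to 77.7 (-1.30). Interferon genes (3 higher, 3 lower of 9; 4 and 3 adjusted over the list alone, and 2 and 3 with TMM scaling; median 0.11, mean -0.38, test downward, adjusted p = 0.477) and immediate early genes (3 and 2 of 11; 3 and 2 adjusted over the list alone, and 1 and 4 with TMM scaling; median -0.03, adjusted p = 0.48) moved both ways. Of 7 erythroid genes 1 rose, Gp9 (1.92; 1 adjusted over the list alone, and 1 higher and 1 lower with TMM scaling; median -0.47, adjusted p = 0.534). Of 11 stroma genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median -0.41, adjusted p = 0.534), with Pdgfrb at 25.4 (3.94). No sex-linked gene passed (0 of 5, and 0 adjusted over the list alone; median 0.10, mean -0.31, test downward, adjusted p = 0.711).

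In all, 5976 genes were called in Pax5-KO, 4451 higher and 1525 lower. With TMM scaling 6399 were called, 3324 higher and 3075 lower. DESeq2 gave 3471 higher and 3132 lower, edgeR 3350 and 3051, and quantile normalization 3016 and 3448. Relative to the median, 1522 called genes were over 2-fold higher and 1125 over 2-fold lower. The groups did not overlap for 6934 genes (54.0%), against 10% by chance.

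The direct contrast of both knockouts asked where loss of EBF1 and loss of PAX5 differ. Pre-B receptor genes were lower in Ebf1-KO than in Pax5-KO. Igll1 differed by a log2 fold change of -8.81 (SE 0.17), Vpreb1 by -8.75, Cd79b by -6.95 and Cd79a by -6.35. Of 20 members 10 were lower and 4 higher (10 and 5 adjusted over the list alone; median -0.61, camera adjusted p = 9.06e-05, and adjusted p = 0.317 with an estimated correlation). B-lineage transcription factors were lower in 9 of 17 cases and higher in 2 (10 and 3 adjusted over the list alone; median -0.69, camera adjusted p = 4.43e-05, and adjusted p = 0.281 with an estimated correlation). Pou2af1 was at 9.84 ± 1.21 against 7872 ± 1772 (-9.53), Erg at 4.34 against 1336 (-8.03) and Ikzf3, the gene of Aiolos, at 38.3 against 412 (-3.45). V(D)J genes split 4 to 4 of 14 (4 and 4 adjusted over the list alone; median -0.13, mean 0.28, test downward, adjusted p = 0.884): Rag1 was lower (-1.83), and Rag2 (1.67) and Dntt (4.79 against 0.965) higher in Ebf1-KO.

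NK, T cell and progenitor genes were higher in Ebf1-KO than in Pax5-KO. In the NK and innate lymphoid list 15 of 17 were higher and none lower (15 adjusted over the list alone; median 3.59, or 3.72 with 1 gene at its bound; camera adjusted p = 5.55e-11, and adjusted p = 0.162 with an estimated correlation). Zbtb16, the gene of PLZF, was at 148 ± 12.3 against 2.49 ± 1.09 (5.42), and Id2 differed by 2.87. In the T lineage list 9 of 15 were higher and 2 lower (10 and 2 adjusted over the list alone; median 1.41, camera adjusted p = 0.00439, and adjusted p = 0.286 with an estimated correlation). Bcl11b (7.15), Gata3 (4.66) and Tcf7 (3.09) were higher, while the Notch target Hes1 (-5.71) and Notch1 (-1.15) were lower. In the stem and progenitor list 9 of 14 were higher and 3 lower (9 and 3 adjusted over the list alone; median 1.33, camera adjusted p = 0.0072, and adjusted p = 0.289 with an estimated correlation). Cd34 (6.13), Kit (3.51) and Hoxa10 (2.93) were among those higher. Erythroid and megakaryocyte genes were higher in 5 of 7 cases (5 adjusted over the list alone; median 1.77, camera adjusted p = 0.0072, and adjusted p = 0.162 with an estimated correlation). Adhesion receptors were higher in 9 of 17 and lower in 2 (10 and 2 adjusted over the list alone; median 0.80, camera adjusted p = 0.00329, and adjusted p = 0.162 with an estimated correlation), with Cd44 at 2061 against 256 (2.98). Interferon genes were higher in 6 of 9 and lower in 1 (7 and 1 adjusted over the list alone; median 1.04, camera adjusted p = 0.0178, and adjusted p = 0.281 with an estimated correlation; call lost without Pax5-KO 3, 0.067). Sex-linked genes differed as against WT (1 higher, 4 lower, and the same adjusted over the list alone; median -8.48, camera adjusted p = 7.64e-05, and adjusted p = 0.162 with an estimated correlation).

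The Myc and ribosome biogenesis list was lower in Ebf1-KO than in Pax5-KO, with 3 of 16 members lower and none higher (2 adjusted over the list alone, and 13 with TMM scaling; median -0.34, camera adjusted p = 0.0341, and adjusted p = 0.823 with an estimated correlation). The list call was lost without Ebf1-KO 1 (0.106), Ebf1-KO 2 (0.0655) or Pax5-KO 3 (0.0873). The members were Gnl3 (-0.70), Myc (-1.23) and Nop56 (-0.57), whose calls were lost without Ebf1-KO 1 (adjusted p = 0.0503, 0.108 and 0.184). Myc also lost its call without Pax5-KO 2 (0.0501) or Pax5-KO 3 (0.066), and Nop56 without WT 2, Ebf1-KO 2, Pax5-KO 2 or Pax5-KO 3 (0.0574, 0.125, 0.0529 and 0.156). The other lists did not pass. Myeloid genes were higher in 7 of 14 and lower in 5 (7 and 5 adjusted over the list alone; median 0.56, adjusted p = 0.534), dendritic genes 4 and 2 of 8 (5 and 2; 0.47, 0.276), and cytokine signalling genes 6 and 2 of 17 (6 and 2, and 5 and 6 with TMM scaling; median -0.08, mean 0.26, test upward, 0.55). Glycolysis genes stood at 3 and 3 of 18 (3 and 3, and 5 and 4 with TMM scaling; 0.07, 0.892), cell cycle genes at 2 and 1 of 20 (1 and 1; median -0.01, mean 0.01, test upward, 0.93), immediate early genes at 2 and 2 of 11 (3 and 2; 0.30, 0.932) and stroma genes at 1 and 1 of 11 (1 and 1; 0.29, 0.884). With TMM scaling 5 cell cycle genes were higher and 2 lower. The cell cycle calls, of Ccne1, Ccne2 and Ccnb2, were all lost without Pax5-KO 2 (limma adjusted p = 0.0896, 0.0642 and 0.0533), and each also without other libraries. In all, 3962 genes differed between the knockouts, 2250 higher and 1712 lower in Ebf1-KO, and 5151 with TMM scaling (2629 and 2522). The groups did not overlap for 5328 genes (41.5%), against 10% by chance.

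Both comparisons with WT were then set against each other. In one direction 4454 genes were called in both, 3376 higher and 1078 lower. The balance rested on the scaling: TMM gave 2370 higher and 2231 lower, edgeR 2365 and 2211, DESeq2 2424 and 2226, and quantile normalization 2113 and 2455. Independent lists of the same sizes would share 1817 and 220.3. Simulated unchanged groups against the same WT libraries shared a mean of 2.63 and 21.2 over 100 simulations, with 207 and 2086 the highest. The fold changes correlated across genes, which are not independent replicates, with r = 0.68 (simulated 0.49, SD 0.31), and their covariance was 1.74 (simulated 0.0250). The 3 WT libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Another 324 genes were called in opposite directions, 122 higher in Ebf1-KO and lower in Pax5-KO and 202 the reverse (0 in the simulations, by limma). The simulated groups were unchanged, and shared WT libraries move both comparisons the same way. That 0 was thus largely set in advance and lends the 324 no support. A mean of at least 5 CPM left 164 genes called in opposite directions (59 and 105), and the test against a fold change of 1.5 called 102 (31 and 71). Other settings gave more: TMM 167 and 235, edgeR 404 (165 and 239), DESeq2 392 (163 and 229), quantile normalization 463 (214 and 249) and the replicate block 486 (188 and 298). Kit (282 in WT, 1342 in Ebf1-KO, 114 in Pax5-KO) and Hes1 (37.4, 1.19 and 95.1) were among them.

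The ATAC comparisons asked whether sites bound by a missing factor lose accessibility more than sites bound by the other. Pax5 transcripts were also low in Ebf1-KO (13.1, against 1521 in WT), and Ebf1 transcripts fell in Pax5-KO. The losses of the factors are therefore not separate, which limits what this question can show. The sites were the authors' re-analysed EBF1 and PAX5 ChIP peaks of earlier studies: 7815 bound by EBF1 only, 5033 by PAX5 only and 1529 by both. Signal is in tags per peak per 10 M tags. At sites bound by both, the mean signal was 25.7 ± 5.65 in WT, 9.50 ± 0.867 in Ebf1-KO and 9.58 ± 1.19 in Pax5-KO (n = 3 libraries each). At EBF1-only sites it was 12.3 ± 2.44, 7.22 ± 0.640 and 6.98 ± 0.780, and at PAX5-only sites 11.5 ± 2.39, 6.13 ± 0.569 and 4.30 ± 0.471. In each class and knockout all 3 libraries lay below all 3 WT libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allow). The share of all tags that fell in these peaks was 1.52 to 2.31% in WT, 0.930 to 1.11% in Ebf1-KO and 0.825 to 1.02% in Pax5-KO.

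**Figure D3:**
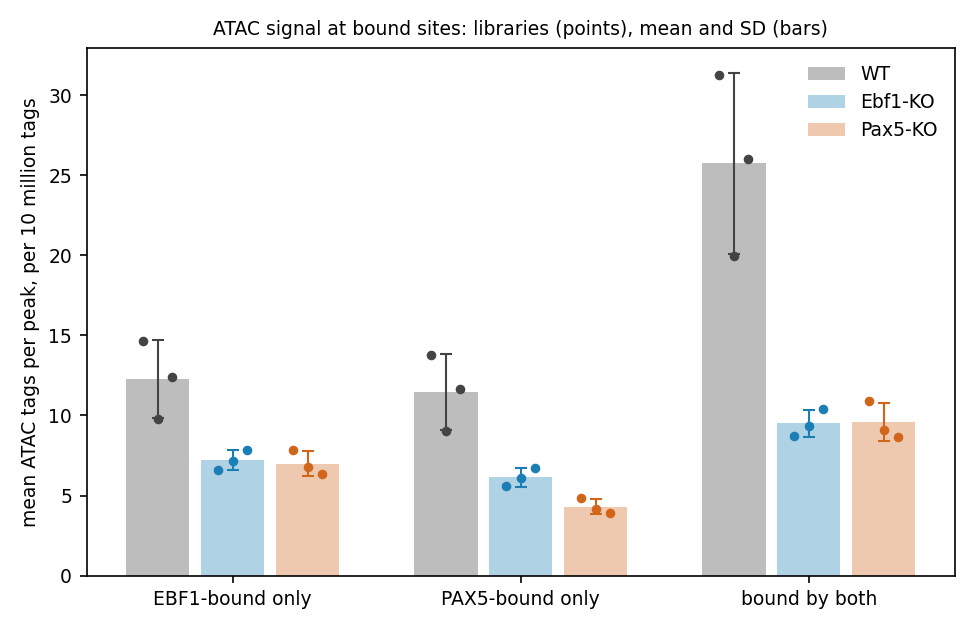
Mean ATAC tags per peak per 10 M tags (y axis) at sites bound by EBF1 only, PAX5 only or both, for WT, Ebf1-KO and Pax5-KO; points are libraries, bars mean and SD. At sites bound by both, signal is 25.7 in WT and 9.50 and 9.58 in the knockouts.

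In Ebf1-KO the median log2 ratio to WT was -0.73 at EBF1-only, -0.96 at PAX5-only and -1.82 at shared sites (SD over libraries 0.06, 0.05 and 0.05). In Pax5-KO it was -0.60, -1.16 and -1.34 (SD 0.11, 0.07 and 0.11). These SDs, and those of the differences that follow, hold no WT spread, since each knockout library was set against the same WT mean. Over all sites PAX5-only lost more than EBF1-only sites, by 0.22 ± 0.01 in Ebf1-KO and 0.58 ± 0.04 in Pax5-KO (exact permutation test of the difference between knockouts, two-sided, p = 0.1, the smallest possible). In Ebf1-KO this ranking was lost beyond 1 kb of a start site, with medians of -1.02 at EBF1-only and -1.01 at PAX5-only sites. In Pax5-KO it held there (-0.58 and -1.20). Within 1 kb lay 25.9% of EBF1-only and 7.47% of PAX5-only sites. By peak, 7817 of 14365 were called in Ebf1-KO, 471 higher and 7346 lower, and 7708 in Pax5-KO, 303 higher and 7405 lower. With TMM scaling over the bound peaks the split was 2929 higher and 4269 lower of 7198 in Ebf1-KO, and 1976 and 3057 of 5033 in Pax5-KO. That scaling also turned the EBF1-only medians to 0.063 and 0.26, while shared sites stayed lower (-0.96 and -0.42). The direct contrast called 3117 peaks, 1301 higher and 1816 lower in Ebf1-KO. Among peaks above the median signal the balance turned (1323 higher, 1234 lower). Of the 3117 calls, at EBF1-only sites 1333 were lower and 397 higher in Ebf1-KO, and at PAX5-only sites 123 were lower and 765 higher. The higher count of all peaks fell without Ebf1-KO 2, Ebf1-KO 3, Pax5-KO 2 or Pax5-KO 3 (862, 655, 851 and 819), as did that at EBF1-only sites (195, 120, 198 and 186), which was 596 without WT 2. The higher count at PAX5-only sites was 459 without Ebf1-KO 3. In each of these settings more EBF1-only peaks were lower than higher in Ebf1-KO, and more PAX5-only peaks higher than lower. With TMM scaling over the bound peaks the direct contrast had 1856 peaks higher and 2221 lower in Ebf1-KO. At EBF1-only sites 718 were higher and 1610 lower, and at PAX5-only sites 930 were higher and 182 lower.

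Sites assigned to named genes by the authors' annotation followed. For key genes the site of highest WT signal was taken, a choice that can by itself enlarge its fall. The Cd79a promoter (chromosome 7, 24897241 to 24897535, mm10; bound by both) had 43.6 ± 9.37 tags in WT, 2.75 ± 0.431 in Ebf1-KO (log2 fold change -3.56, adjusted p = 3.49e-21) and 13.0 ± 1.01 in Pax5-KO (-1.66, adjusted p = 1.37e-07). The Igll1 promoter (chromosome 16, 16863976 to 16864343; both) fell from 62.5 ± 11.7 to 4.36 ± 1.21 and 21.8 ± 4.60. A PAX5-only site 25757 bp upstream of Rag2 (chromosome 2, 101598867 to 101599115) fell from 37.6 to 1.43 and 3.08, and a shared intergenic site 175719 bp from the Foxo1 start site (chromosome 3, 52443859 to 52444253) from 54.3 to 10.6 and 18.6. Some sites rose. An EBF1-only site 13489 bp upstream of Csf1r, the receptor gene of macrophage colony-stimulating factor (chromosome 18, 61091948 to 61092218), rose from 4.42 ± 1.36 to 11.8 ± 3.08 in Pax5-KO (1.25, adjusted p = 4.73e-04) and stood at 3.54 ± 0.681 in Ebf1-KO (adjusted p = 0.556). A PAX5-only site in Mrgpra1 (chromosome 7, 47346078 to 47346326) rose from 3.14 to 52.3 in Ebf1-KO (3.76) and 22.3 in Pax5-KO (2.55), both also with TMM scaling.

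Binding and expression were joined through the authors' nearest-gene annotation. Of the genes lower in Pax5-KO, 39.7% had a PAX5 site, against 18.6% of the genes not called (odds ratio 2.88, Fisher's exact test, adjusted p = 5.46e-64). Of those higher, 22.9% had such a site (odds ratio 1.30, exact test, adjusted p = 4.36e-08). Of the genes lower in Ebf1-KO, 48.1% had an EBF1 site (odds ratio 1.97, Fisher's exact test, adjusted p = 5.79e-35), and the genes higher gave a lower ratio (odds ratio 1.20, exact test, adjusted p = 1.09e-05). The other factor's sites gave like values: PAX5 sites an odds ratio of 2.88 for genes lower and 1.34 for genes higher in Ebf1-KO, and EBF1 sites 1.89 and 1.21 in Pax5-KO (8 tests, Benjamini-Hochberg adjusted, two-sided). Since Pax5 transcripts were also low in Ebf1-KO, and Ebf1 transcripts lower in Pax5-KO, these values cannot tell the factors apart. Genes are not independent replicates, and the odds ratio of lower genes against that of higher genes was not tested. It also depended on the scaling: with TMM calls PAX5 sites gave 2.37 and 1.65 in Pax5-KO.

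The authors' pooled profiles gave ATAC coverage at ChIP peaks on genes they called. At PAX5 peaks of genes higher in WT than in Pax5-KO, coverage within 250 bp of the centre in Pax5-KO was 0.324 of WT, and in Ebf1-KO 0.384. At PAX5 peaks of genes lower in WT the ratios were 0.541 and 0.644. At EBF1 peaks the ratio in Ebf1-KO was 0.395 for genes higher in WT and 0.693 for genes lower. At WT ATAC peaks near genes linked to a sub-fraction of common lymphoid progenitors it was 0.583. These pooled columns hold 1 value per genotype, so no test was made, and the peaks were chosen by genes called on these libraries. The ratios in the flanks beyond 2000 bp also differed between sets. At PAX5 peaks they were 0.735 in Pax5-KO and 0.729 in Ebf1-KO for genes higher in WT, and 0.996 and 0.991 for genes lower. At EBF1 peaks they were 0.759 and 1.05. Part of the contrast between higher and lower genes thus lay outside the peaks. Near the progenitor genes the flanks were at 0.652, so most of that loss was not specific to the peak centre.

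**Figure D4:**
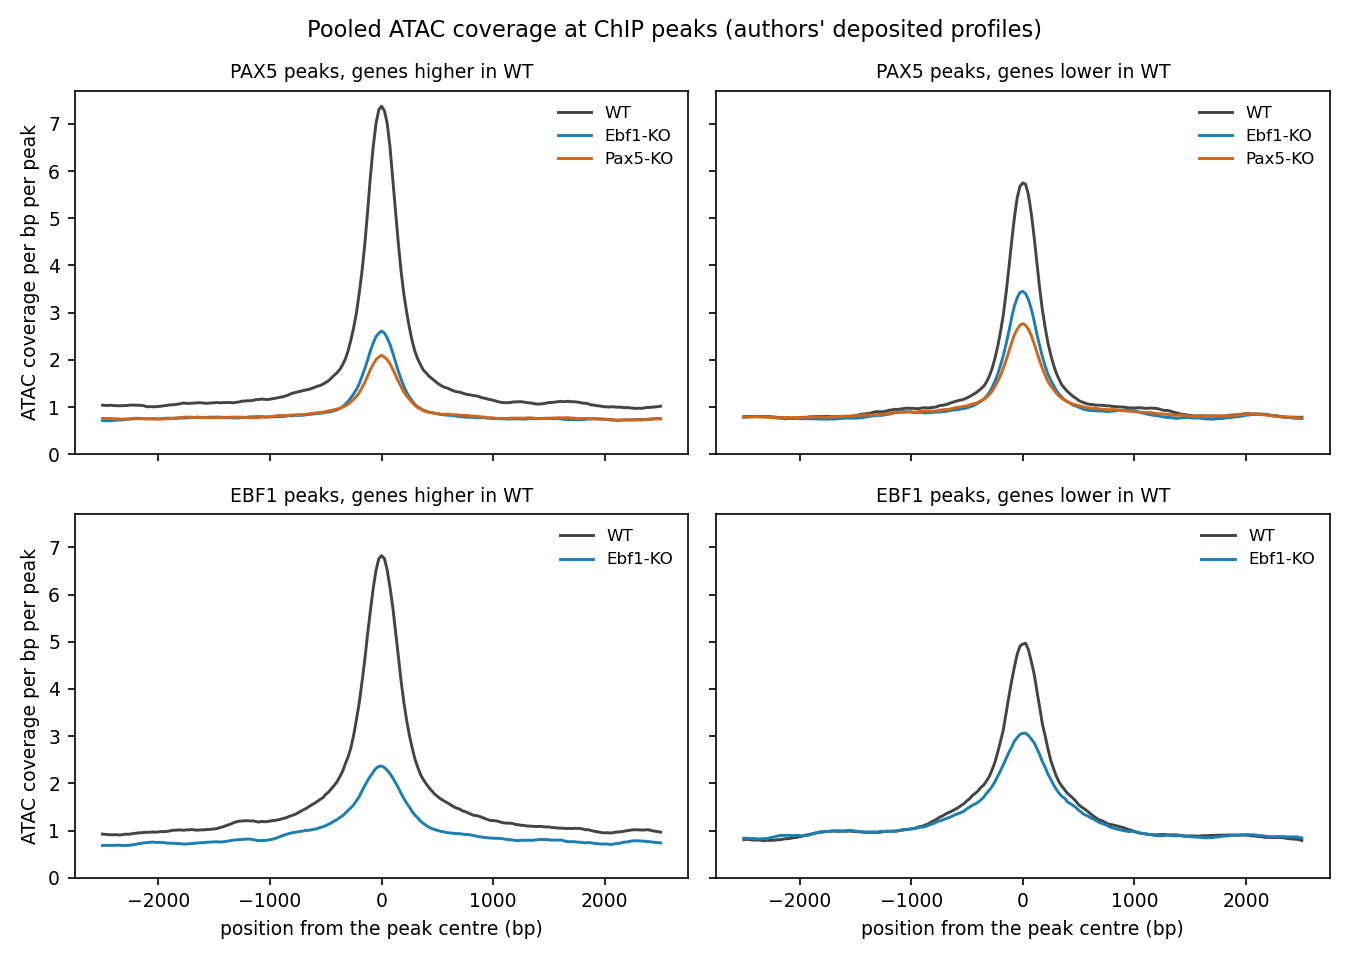
ATAC coverage per bp per peak (y axis) against position from the peak centre in bp (x axis), pooled by genotype as in the authors' deposited profiles, at PAX5 and EBF1 peaks of genes higher or lower in WT. Pax5-KO coverage at PAX5 peaks of genes higher in WT is 0.324 of WT within 250 bp.

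The authors' deposited table of genes lower in Ebf1-KO held 1986 genes, of which 1591 were tested here and 1520 (95.5%) were called lower. For genes higher in Ebf1-KO 2056 of 2061 were called the same way and 1 the opposite way. In Pax5-KO the shares of the authors' deposited tables were 96.2% of 1179 lower and 99.3% of 1681 higher genes. These tables come from the same libraries, so they are not independent evidence.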

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

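The tests of the 3 patterns below were all chosen after the pattern was seen, while the count of splits was planned.

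More genes were higher than lower in both knockouts, with medians of 0.31 in Ebf1-KO and 0.28 in Pax5-KO. A low WT 1 library was argued against as the whole cause, since the medians without it were 0.23 and 0.20. With each library scaled to its own reads in exons the medians fell to 0.056 and 0.069, so most of the shift went with the lower exon share of the WT libraries. That share is the sum of the same gene values over mapped reads. This scaling therefore cannot tell a technical difference from a general rise of transcripts. With that scaling 57.7 and 58.1% of the called genes were still higher. A difference in total RNA per cell stays open as untested.

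ATAC signal was lower at the bound sites of either factor in either knockout. If a lower share of tags in open chromatin acted on all sites alike, EBF1-only sites within 1 kb of a start site would lose as much as those beyond. In Ebf1-KO the near sites lost 33.5% of the far loss (-0.34 against -1.02, libraries 21.5 to 43.9%), which argues against it as the whole cause. In Pax5-KO the figure was 106% (-0.62 against -0.58, libraries 88.8 to 104%), so a general loss of tags in peaks may explain the lower EBF1-only signal there. A high WT 1 library was argued against, since the medians over all peaks without it were -0.80 and -0.71, against -0.89 and -0.81 with it.

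Xist was high and Y-linked transcripts were near 0 in all 3 Ebf1-KO libraries, the reverse of the other 6. Genes on X and Y were 2.90% of the genes called in Ebf1-KO (206) and were called in 51.1% of cases, against 55.4% of autosomal genes, which argues against the sex chromosomes as the source of the count. For an exchanged library, 0 libraries lay on the wrong side for both Pax5 and Cd79a, which argues against it. Sex of the embryos is confounded with the Ebf1-KO genotype here, and effects of sex on autosomal genes stay open.

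Some named genes were called in opposite directions against WT. Their direct contrast follows from that choice and is no further test, so its size alone is given, as Ebf1-KO minus Pax5-KO log2 difference less the median. Kit (3.51), Cd44 (2.98), Pfkp (1.92), Polm (5.06) and Sox6 (9.38) were higher in Ebf1-KO than in Pax5-KO. Hes1 (-5.71) and Pcdh11x (-8.70) were lower. The fall of Sox6 in Pax5-KO rests on low values that overlap between groups (0.634 to 2.13, against 1.76 to 4.77 in WT). Polm rose from 26.4 in WT to 44.7 in Ebf1-KO. The V(D)J list that holds it had 2 members higher there, and 1 with TMM scaling.

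The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real RNA splits called 7095, 5976 and 3962 genes (Ebf1-KO, Pax5-KO, direct contrast), 1 of 10 splits each, and no other split called any by limma (at most 405, 1484 and 1112 at an unadjusted p under 0.05, real 7697, 6929 and 4943). The real ATAC splits called 7817, 7708 and 3117 peaks, also 1 of 10 each, and the others 0 by limma (at most 734, 1523 and 736 unadjusted, real 8408, 8416 and 4725). Every other split mixed genotypes within its groups, which widens the spread and lowers the counts of genes and peaks. The real splits were thus favoured in advance, so these counts cannot exclude chance. For gene lists the real split called 7 in Ebf1-KO against at most 11 in another split (7 of 10 called as many), 9 in Pax5-KO against 9 (2 of 10), and 10 in the direct contrast against 9 (1 of 10). The RNA numbers pair the samples, and 4 of the 10 splits part all pairs: among the others of these the highest list counts were 9, 6 and 6, against 11, 9 and 9 where a pair stays together. For the overlap 1 of 100 regroupings of the 9 libraries gave as many genes as the real 4454, the real one itself, with 3040 the highest other. Of 108 regroupings that keep 1 library of each number in each group, 100 were drawn after this was seen, and again only the real one gave as many, with 2892 the highest other. No other regrouping drawn thus matched the real overlap, also with the numbers kept together. Of the 100 drawn last, 97 mixed genotypes within a group, which widens the spread there and lowers the count. The real grouping was therefore favoured in advance, so chance is not excluded as a source of the overlap.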

How the results depend on the processing

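The edgeR and TMM fits of RNA, the fits without X and Y, scalings and left-out libraries of list tests, TMM calls for bound genes, edgeR for ATAC and the direct ATAC contrast were chosen after the result was seen. Scaling to all mapped reads or tags, without TMM, equals the scaling used by construction and was not run separately. Scaling RNA to reads in exons was also chosen after the result was seen. It gave 7426 calls in Ebf1-KO (4285 higher, 3141 lower) and 6496 in Pax5-KO (3771 higher, 2725 lower). Genes with a mean of at least 5 CPM gave 4584, 3909 and 2093 calls (Ebf1-KO, Pax5-KO, direct contrast) and 2969 shared, and a test against a fold change of 1.5 gave 3458, 2453, 2089 and 1768. With the replicate block 8783, 8073 and 5622 genes were called and 6106 shared. Without 1 library the counts were 6077 to 7635, 4872 to 6380, 3353 to 4226 and 3589 to 4636. For lists, an estimated correlation left 0 calls by camera (14 at an unadjusted p under 0.05; fry 33, keeping 24 of the 26), the block gave 27, keeping all 26, and 24 to 29 were called without 1 library. For ATAC, peaks above the median signal gave 4300 and 4948 (Ebf1-KO, Pax5-KO), a test against a fold change of 1.5 gave 5002, 4000 and 844 (direct contrast last), TMM 5033 in Pax5-KO, and the block 7818, 7696 and 3136. Without 1 library the counts were 7112 to 8115, 6507 to 8235 and 2164 to 3614. ATAC class medians follow in the order EBF1-only, PAX5-only, both. With TMM they were 0.063, -0.17 and -0.96 in Ebf1-KO and 0.26, -0.32 and -0.42 in Pax5-KO, so the EBF1-only medians turned direction. With pseudocount 1 they were -0.65, -0.84 and -1.69 in Ebf1-KO and -1.04 at PAX5-only sites in Pax5-KO. With pseudocount 5 they were -0.38, -0.46 and -1.18, and -0.35, -0.60 and -0.97. Above the median WT signal they were -0.85, -1.43 and -2.02, and -0.86, -1.76 and -1.48. Those peaks were chosen by the same WT values that enter the ratio, which can by itself enlarge the loss. Beyond 1 kb of a start site they were -1.02, -1.01 and -1.91 in Ebf1-KO. Without 1 library they ranged from -0.79 to -0.65, -1.04 to -0.86 and -1.93 to -1.73 in Ebf1-KO, and from -0.70 to -0.50, -1.25 to -1.05 and -1.49 to -1.21 in Pax5-KO. Profile ratios over 100 and 500 bp were 0.358 and 0.421 (PAX5 peaks, genes higher in WT, Ebf1-KO), 0.291 and 0.375 (same, Pax5-KO), 0.609 and 0.688 (genes lower in WT, Ebf1-KO), 0.492 and 0.610 (same, Pax5-KO), 0.357 and 0.446 (EBF1 peaks, higher), 0.634 and 0.754 (lower), and 0.578 and 0.595 (progenitor genes). Named genes kept a call in 5212 cases, were not called in either fit in 135, gained a call in 11 and lost it in 177, 44 of these under the 1.5-fold test, and none turned. Named peaks kept it in 701, were not called in either fit in 148, gained it in 9 and lost it in 26. With TMM 4 turned: Dntt to 0.0058 in Ebf1-KO, and Vpreb1 to 0.13, Dntt to 0.16 and Flt3 to 0.036 in Pax5-KO. Single list tests kept the call in 329, were not called in either fit in 367, gained it in 25 and lost it in 35 (26 with an estimated correlation). The 8 odds ratios of bound genes kept their calls and directions under the 4 alternatives run. With TMM calls the ratios of lower and higher genes drew closer. For PAX5 sites they were 2.37 and 1.65 in Pax5-KO and 2.26 and 1.78 in Ebf1-KO. For EBF1 sites they were 1.68 and 1.35 in Ebf1-KO and 1.58 and 1.30 in Pax5-KO.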

Other observations

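The palindrome test was planned, its settings by position and WT signal were chosen after the result was seen, and the other values here were read from the tables without a further test.

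Genes called in opposite directions by the 2 knockouts included surface and signalling genes, chosen here after their values were seen. Kit and Cd44, surface molecules of progenitors and lymphocytes, were higher in Ebf1-KO (1342 and 2061) than in WT (282 and 729) and lower in Pax5-KO (114 and 256). Sox6 rose from 3.23 to 1540 in Ebf1-KO and was at 1.30 in Pax5-KO, where its low values overlapped those of WT. Rasgrp3, an activator of Ras, fell from 74.5 to 4.25 in Ebf1-KO and rose to 1888 in Pax5-KO. Lin28b, a fetal regulator of let-7, was at 253 in WT, 60.4 in Ebf1-KO and 1663 in Pax5-KO, and Dpp4 at 891, 16.8 and 1737.

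ATAC signal at bound sites went with the call of the nearest gene. In Ebf1-KO the median log2 ratio at shared sites was -2.35 for genes lower, -1.65 for genes not called and -1.29 for genes higher, and at EBF1-only sites -1.33, -0.58 and -0.53. In Pax5-KO it was -1.83, -1.20 and -1.06 at shared sites and -1.48, -1.10 and -0.996 at PAX5-only sites. The order was the same at sites of the other factor alone. There the medians were -1.34, -0.92 and -0.68 at PAX5-only sites in Ebf1-KO, and -0.85, -0.62 and -0.50 at EBF1-only sites in Pax5-KO. The order was thus not particular to sites of the missing factor. No test was made, since peaks of one gene are not independent.

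The palindrome TCCCNNGGGA lay in 27.2% of EBF1-only peaks, 14.1% of shared peaks and 0.775% of PAX5-only peaks. In Ebf1-KO EBF1-only peaks with it differed from those without by -0.10, by 0.18 beyond 1 kb of a start site, by -0.23 less the median of the WT signal decile and by -0.17 with both. As the sign turned with position, these settings leave open whether such peaks lose more. In Pax5-KO the difference was 0.29, and 0.0045 less the decile median, which argues against a larger loss there. The difference between the knockouts was -0.40 and -0.26 with both corrections. No p is given, since single peaks were permuted and peaks in the same 3 libraries per group, or near one gene, are not independent. Direct dependence of these sites on EBF1 remains a hypothesis, and peaks with the palindrome also had lower WT signal (medians 4.49 and 9.85).

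Some further calls changed when 1 library was left out, most of them with any of several libraries. In Ebf1-KO against WT, Csf1r (main adjusted p 0.0139) was at 0.0789 without WT 2, 0.0526 without Ebf1-KO 2 and 0.0584 without Ebf1-KO 3. Fbn1 (0.0122) was at 0.0769 without WT 1, 0.0525 without WT 3 and 0.0611 without Ebf1-KO 3. In Pax5-KO Fos (0.0282) was at 0.0789, 0.062 and 0.0573 without WT 1, 2 and 3 and at 0.116 without Pax5-KO 2. Atf3 (0.024) was at 0.0769 and 0.0632 without WT 2 and 3 and at 0.106 without Pax5-KO 2. In the direct contrast Blnk (0.211) passed only without Pax5-KO 3 (0.0198). Among peaks in Pax5-KO, the Vpreb1 promoter (0.0379) was at 0.202 without WT 1, 0.083 without WT 3, 0.165 without Pax5-KO 2 and 0.205 without Pax5-KO 3. The Dntt site (0.0267) was at 0.109 without WT 1 or WT 3 and at 0.191 without Pax5-KO 3. The Kit site in Ebf1-KO (0.0112) was at 0.185 without Ebf1-KO 2 and kept its call without any other library. All these adjusted p-values are from limma without the replicate block. With all libraries, that block kept every RNA gene call of the test reported.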
